A study of Mus musculus with 227 samples.

How the data were processed

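Single cells from long bones of BL6 mice at postnatal day 3 were sorted by flow cytometry, captured on the Fluidigm C1 platform and sequenced as SMARTer and Nextera XT libraries with ERCC spike-ins. The labels state that capture sites were imaged and that only single live cells were included; a bulk RNA control and a control without cells were processed per run and are not analysed here. The values used were FPKM (fragments per kilobase of transcript, scaled to mapped fragments) as deposited by the authors, in 1 table with 24388 genes and 92 spike-ins for each cell. Per the submitters' processing notes reads were handled on the mm10 build with SAMtools. The aligner, the program that estimated FPKM, the annotation and the cell filters are not given in the sources used here. FPKM values are estimated abundances from which whole reads cannot be recovered, so depth per cell is unknown. The table holds 0 mitochondrial genes, so their share could not be computed. Coordinates were taken from GENCODE for the mm10 assembly.

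Each table column was matched to its cell by the index names in the labels, with 0 columns unmatched, and no 2 columns were identical. Index positions place mSSC and CSP cells on 1 plate, THY+ on another and 6C3+ on another, 3 in all. Each population counted as 1 sample, since no animal or culture is named; no p-value was computed. A gene counted as detected in a cell at FPKM of at least 1. Shares of cells have exact Clopper-Pearson 95% intervals, which cover counting error between cells only; at 0 cells the upper bound of that interval is given, as a limit on cells with the gene detected. A gene listed at 0 is not shown to be absent from the cell.

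The 4 comparisons were CSP minus mSSC, THY+ minus CSP, 6C3+ minus CSP and 6C3+ minus THY+, each as the difference of mean log2(FPKM + 1). For 24 gene lists and the 84 ribosomal protein genes, the median difference over all measured members is given. The percentile ranks the median over members with a mean log2 level above that of a value of 0. It was placed among 10000 random lists matched on mean level in 20 bins, as a description of these libraries. The ranked median can therefore differ from the printed one. In CSP minus mSSC 3 of 4 hypertrophic chondrocyte and 8 of 12 fibroblast and periosteal genes were ranked. The lists were osteoblast, chondrocyte, hypertrophic chondrocyte, fibroblast and periosteal, tendon, marrow stroma, adipocyte, pericyte and smooth muscle, endothelial, myeloid, pre-B, erythroid, skeletal muscle, osteoclast, Schwann, BMP, WNT, hedgehog, TGF beta, limb patterning, proliferation, dissociation stress, housekeeping and sort antigen transcripts. Cnmd was found under its older symbol Lect1, and 7 of 8 erythroid genes were matched. Named genes were, per comparison, the 12 with the highest and the 12 with the lowest difference among genes detected in at least 50% of the cells of the higher population, up to 4 members of each list with the largest absolute difference, and all sort antigen transcripts; gene models without a name, pseudogenes, ribosomal and sex-linked marker genes were left out. Other list members named in the text were chosen after their values were seen. The lists, comparisons and this rule were fixed before the data were examined. The repeat on cells with at least 1000 genes applied the same rule and was chosen after seeing the data.

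Each population was clustered alone on the 500 most variable genes detected in at least 10% of its cells, with 10 principal components, Ward clustering and 2 to 6 clusters by silhouette. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9 were used. Alternatives were pseudocounts of 0.1 and 10, FPKM rescaled to 1000000 per cell, the log2 of the mean, genes at mean FPKM of at least 1, detection above 0 or at 10, cells without the lowest 10%, cells matched on detected genes (2020.6 to 3068.7), cells without endothelial transcripts, 1000 variable genes, 20 components and k-means. Added after seeing the data were cells with at least 1000 genes, at least 2000 genes, and at least 1000 genes with rescaling.

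The comparison was tested on simulated data with genes planted at 4-fold and 16-fold differences in either direction. From 92% to 100% of the planted genes had the right sign in each comparison, and of 100 unchanged lists 6, 3, 4 and 0 lay outside the central 95% of random lists. In CSP minus mSSC, genes planted 4-fold higher and 4-fold lower had median differences of 1.76 and -1.22. The real all-cell comparison had a median of -1.43 over all genes with mean log2 above 1, a shift the simulated values do not show. These rates therefore do not cover all-cell comparisons between populations that differ in gene number. Whether they hold at the cell numbers of the comparisons with at least 1000 genes, or for lists of rarely detected genes, was not tested. A first simulation of the clustering, with cells drawn with replacement, did not recover the planted groups: it gave 6 clusters in each population and adjusted Rand indices of -0.003 to 0.289. That simulation held copies of the same cell, so it was changed after this result. With cells drawn without replacement, the index was 1 in mSSC, CSP and 6C3+ and 0.657 in THY+. In the clustering simulations with planted groups, 200 genes were each set to 0 in 1 group and raised 16-fold in the other. Recovery of this on-off signal does not show that weaker groups would be found. Values shuffled over cells with nothing planted still gave 6 clusters in mSSC, THY+ and 6C3+ and 3 in CSP, so the number of clusters alone does not show structure.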

Results

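The series profiled single cells from the long bones of BL6 mice at postnatal day 3, sorted into 4 populations by surface antigens. There were 37 cells labelled mSSC, 26 labelled CSP, 72 THY+ and 92 6C3+. The gates shared absence of CD45 and Ter119 and presence of AlphaV integrin, and all but the 6C3+ gate named absence of Tie2. THY+ cells were Thy+6C3-CD105+, 6C3+ cells Thy-6C3+CD105+, CSP cells Thy-6C3-CD105+ and mSSC cells Thy-6C3-CD105-CD200+. The series describes them as skeletal stem, progenitor and stromal populations, and the comparisons ask which transcripts set them apart.

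Each library was 1 cell and no animal or culture was named, so each population counted as 1 sample. Differences between populations therefore have no replicate check and carry no p-value. Shares of cells are given with exact Clopper-Pearson 95% intervals in parentheses, which cover counting error only. Depth in reads is unknown.

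Numbers of detected genes (FPKM of at least 1) lay in 2 ranges. The median was 2534 genes in mSSC, 2019.5 in THY+, 566 in CSP and 410.5 in 6C3+ cells. No mSSC cell had under 1000 genes, against 15 of 26 CSP cells (57.7%, 36.9 to 76.6), 29 of 72 THY+ cells (40.3%, 28.9 to 52.5) and 58 of 92 6C3+ cells (63%, 52.3 to 72.9). Only 11 cells of all 4 populations had between 750 and 1500 genes. In cells under 1000 genes the 6 housekeeping genes were listed at 0 in 28.4% (Actb) to 94.1% (Gapdh) of cells. With at least 1000 genes these 2 were listed at 0 in 0% and 13.6%. Malat1, a nuclear noncoding RNA, was listed at 0 in 0.98% of cells under 1000 genes. ERCC spike-ins took a median of 52.8% of FPKM in THY+ and 75.8% in 6C3+ cells but 0.0012% in mSSC and 0.0038% in CSP cells, so the plates differ in spike-in level. It differed by index row within a plate as well: the 10 THY+ cells of the first row held 0.408% to 7.56%, against a median of 91.9% outside the first 2 rows. Part of that gap goes with gene number. Among THY+ cells with at least 1000 genes the median was 1.06% in the first row and 35.5% outside the first 2 rows. Because of the range in gene number, the comparisons were made for all cells and again for the cells with at least 1000 genes, which were 37 mSSC, 11 CSP, 43 THY+ and 34 6C3+ cells.

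**Figure D1:**
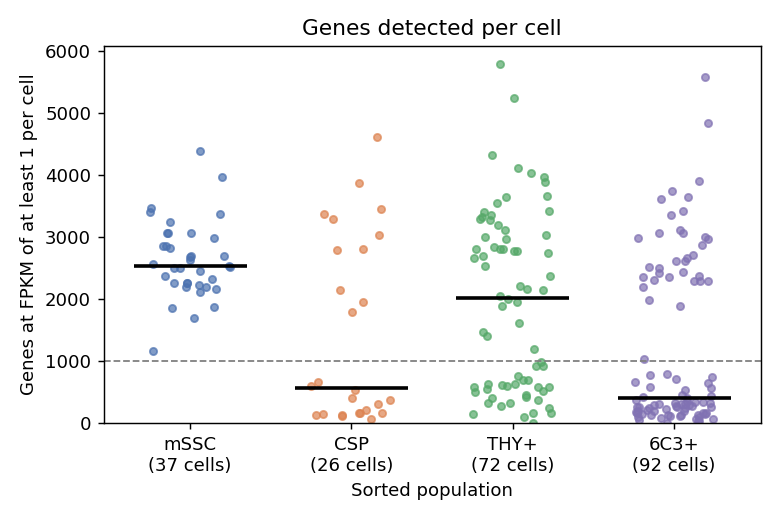
Genes at FPKM of at least 1 in each cell (vertical axis, number of genes) by sorted population; each point is 1 cell, the bar is the median and the dashed line marks 1000 genes. The medians are 2534 in mSSC, 566 in CSP, 2019.5 in THY+ and 410.5 in 6C3+ cells.

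Among transcripts of the sort antigens, Thy1 was detected in THY+ cells alone and Enpep most often in 6C3+ cells. Thy1 was detected in 9 of 43 cells (20.9%, 10 to 36) among THY+ cells with at least 1000 genes and in no cell of another population. Enpep, which encodes 6C3, was detected in 9 of 34 cells (26.5%, 12.9 to 44.4) of 6C3+ and 3 of 43 cells (6.98%, 1.46 to 19.1) of THY+, with overlapping intervals. Itgav, which encodes AlphaV integrin, was found in every population, from 60.5% of THY+ to 64.9% of mSSC cells with at least 1000 genes. Ptprc (CD45) was not detected in any cell. Tek (Tie2) was detected in 1 of 92 6C3+ cells, whose gate does not name Tie2, and in none of the others.

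Between mSSC and CSP the gates set no order for CD200, Cd200 was detected more often in CSP, and Eng gave no clear reading. Cd200 was detected in 9 of 11 cells (81.8%, 48.2 to 97.7) of CSP with at least 1000 genes and in 8 of 37 cells (21.6%, 9.83 to 38.2) of mSSC, although CD200 was a positive gate for mSSC and is not named for CSP. Over all CSP cells the share was 9 of 26 cells (34.6%, 17.2 to 55.7), which overlaps that of mSSC. Eng, which encodes CD105, was detected in 8 of 37 cells (21.6%, 9.83 to 38.2) of mSSC, gated as CD105-, and in 0 of 11 cells (0%, 0 to 28.5) of CSP, gated as CD105+; these intervals overlap. In the other CD105+ gates Eng was detected in 3 of 34 cells (8.82%, 1.86 to 23.7) of 6C3+ and 10 of 43 cells (23.3%, 11.8 to 38.6) of THY+, so few cells with the transcript are not particular to CSP. Both populations are therefore called cells labelled mSSC and cells labelled CSP, and each direction between them below rests on those labels. In the mm10 build Cd200 lies on chromosome 16 (45382135 to 45409053, minus strand) and Eng on chromosome 2 (32646595 to 32682669, plus strand).

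**Figure D2:**
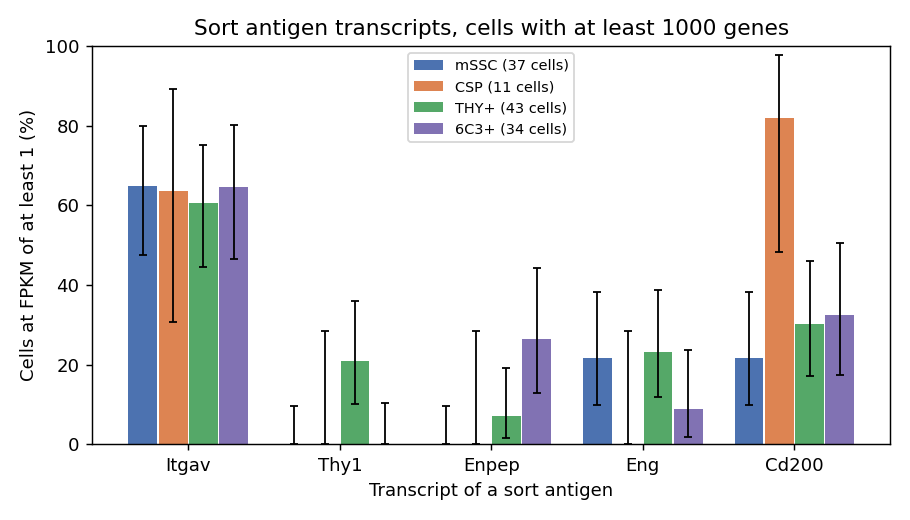
Percent of cells at FPKM of at least 1 (vertical axis) for 5 sort antigen transcripts in cells with at least 1000 genes, by population; error bars are exact 95% intervals for counting error. Cd200 reaches 81.8% in CSP and 21.6% in mSSC cells, and Thy1 appears in THY+ cells alone.

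Pth1r, Ihh, Col10a1 and Panx3 were detected more often in cells labelled CSP than in cells labelled mSSC. Pth1r, the receptor of parathyroid hormone and its related peptide, which the lists used here place with osteoblast and not with hypertrophic chondrocyte genes, was detected in 19 of 26 cells (73.1%, 52.2 to 88.4) of CSP and 10 of 37 cells (27%, 13.8 to 44.1) of mSSC, a difference of 4.34 in mean log2(FPKM + 1). Ihh, the hedgehog ligand of prehypertrophic chondrocytes, was detected in 14 of 26 cells (53.8%, 33.4 to 73.4) against 2 of 37 cells (5.41%, 0.661 to 18.2). Col10a1, the collagen of hypertrophic cartilage, was detected in 12 of 26 cells (46.2%, 26.6 to 66.6) against 3 of 37 cells (8.11%, 1.70 to 21.9), and Panx3 in 11 of 26 against 4 of 37. Lower in CSP were Ucma, a cartilage matrix protein (-7.86; 12 of 26 against 33 of 37 cells), Cytl1 (-7.31; 7 of 26 against 28 of 37) and Fstl1 (-6.78). These values are over all cells, and 15 of 26 CSP but no mSSC cells had under 1000 genes. Fstl1 was also among the 10 leading genes of the clusters with more detected genes in THY+ and 6C3+ cells.

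Among cells with at least 1000 genes the differences in Pth1r, Ihh and Panx3 were wider. Pth1r was found in 11 of 11 CSP cells (median FPKM 376) and differed by 6.87. Panx3 differed by 5.79 (9 of 11 against 4 of 37), Ihh by 5.32 (9 of 11 against 2 of 37), Smpd3 by 5.38 and the pyrophosphatase Ppa1 by 6.34. Cytl1 (-6.89; 2 of 11 against 28 of 37), Kazald1 (-5.22), Ucma (-5.03), the transcription factor Nfib (-4.42; 3 of 11 against 34 of 37) and Fcgrt (-4.87; 0 of 11 against 22 of 37) were lower. Pth1r lies on chromosome 9 (110722085 to 110747145, minus strand) and Ihh on chromosome 1 (74945315 to 74951672, minus strand) of mm10.

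The hypertrophic chondrocyte list had 3 higher and 0 lower of 4 measured, with a median difference of 2.43 over all cells and 4.53 with at least 1000 genes, at percentiles 100 and 100 of random lists matched on level, a description of these libraries. The osteoblast list was higher (median 0.43 over all cells, 10 higher and 4 lower of 15, percentile 100, and 1.19 with at least 1000 genes, 11 higher and 3 lower, percentile 100), led, with at least 1000 genes, by Pth1r, Alpl (4 of 11 against 0 of 37) and Dlx5 (8 of 11 against 6 of 37), genes that growth plate chondrocytes also express. The bone collagen gene Col1a1 was lower (1 of 11 against 22 of 37). General chondrocyte genes were found in both populations: Col2a1 was detected in 10 of 11 CSP and 35 of 37 mSSC cells with at least 1000 genes, and the list's median was 0.17 at percentile 68.8. Over all cells 15 of 15 chondrocyte genes were lower in CSP (median -3.11), at percentile 85.7 of random lists matched on level. Most random lists of that level fell further, so the values show no loss particular to chondrocyte genes. The median over all genes with mean log2 above 1 was -1.43 over all cells and 0.20 with at least 1000 genes.

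Proliferation genes were lower in CSP (median -0.71 over all cells, 0 higher and 17 lower of 17, percentile 0.1, and -0.67 with at least 1000 genes, 4 higher and 13 lower, percentile 0). With at least 1000 genes Cdk1 was detected in 0 of 11 CSP and 5 of 37 mSSC cells and Top2a in 0 of 11 and 5 of 37, shares whose counting intervals overlap. Limb patterning genes were lower (median -0.45 over all cells, 0 higher and 15 lower of 17, percentile 1.3, and -0.37 with at least 1000 genes, 1 higher and 14 lower, percentile 0.1), with Hoxa10 in 1 of 11 against 17 of 37. The dissociation stress list (median -3.75 over all cells, 0 higher and 15 lower of 15, percentile 21.9, and -0.82 with at least 1000 genes, 3 higher and 12 lower, percentile 2.2) lay inside the central 95% of random lists over all cells. Ribosomal protein genes were lower (median -5.30 over all cells, 1 higher and 81 lower of 84, percentile 0, and -0.64 with at least 1000 genes, 11 higher and 71 lower, percentile 0.1), but lay at percentile 36.5 with the log2 of the mean. With at least 1000 genes their median share of endogenous FPKM was alike, 12.1% in CSP and 12.4% in mSSC cells. The median endogenous total there was 578425 FPKM in CSP and 906237 in mSSC cells, so lower values do not mean a lower share. In cells matched on detected genes, 4 of them CSP, the proliferation (percentile 28) and limb patterning lists (20.8) lay inside the central 95%. These cells shared an index plate, so the index plate does not separate them. Which capture run each cell came from was not used here, so a difference in run was not tested. The share of CSP cells under 1000 genes weighs on every all-cell difference, and 11 CSP cells remain above that number.

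Col1a1, Col3a1 and Postn were higher and chondrocyte genes lower in THY+ cells than in cells labelled CSP. Col1a1, the main collagen of bone and tendon, was detected in 70 of 72 cells (97.2%, 90.3 to 99.7) of THY+ and 2 of 26 cells (7.69%, 0.946 to 25.1) of CSP, a difference of 9.36. Col3a1 differed by 6.65 (64 of 72 against 5 of 26) and Postn, a periosteal matrix protein, by 5.74 (55 of 72 against 1 of 26). Matn1, a cartilage matrilin, was detected in 3 of 72 cells (4.17%, 0.868 to 11.7) of THY+ and 16 of 26 cells (61.5%, 40.6 to 79.8) of CSP. Col9a2 (-6.17), Col2a1 (-5.61), Pth1r (-4.82) and Lect1, which encodes chondromodulin (-4.49), were lower too.

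The contrast was wider in cells with at least 1000 genes. Col1a1 differed by 10.09, Lgals1 by 8.93 (41 of 43 against 1 of 11), Postn by 8.06 and the basement membrane collagen gene Col4a1 by 6.34 (36 of 43 against 0 of 11). Cav1, a caveolae protein, was detected in 34 of 43 THY+ and 0 of 11 CSP cells. Matn1 (-9.77), Lect1 (-9.32), Mia (-9.24), Col9a2 (-8.93) and Chad (-7.42) were lower. Median FPKM of Col2a1 was 7.66 in THY+ and 22906 in CSP. Col1a1 lies on chromosome 11 (94936224 to 94953042, plus strand) and Matn1 on chromosome 4 (130944385 to 130955475, plus strand) of mm10.

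By list, 15 of 15 chondrocyte genes were lower in THY+, with medians of -3.56 over all cells and -6.79 with at least 1000 genes (percentile 0 in both). Ihh and Col10a1 were not detected in any of the 72 THY+ cells. Tendon genes were higher (median 1.16 over all cells, 7 higher and 0 lower of 7, percentile 99.9, and 1.99 with at least 1000 genes, 5 higher and 2 lower, percentile 100), among them Tnc (45 of 72 against 3 of 26), Tnmd (23 of 72 against 1 of 26) and Thbs4 (22 of 72 against 0 of 26). Marrow stroma genes were higher (median 0.59 over all cells, 9 higher and 1 lower of 10, percentile 100, and 0.87 with at least 1000 genes, 8 higher and 2 lower, percentile 99.9), with Ebf1 (26 of 72 against 5 of 26) and the stem cell factor gene Kitl (12 of 72 against 0 of 26). Proliferation genes were higher (median 0.63 over all cells, 17 higher and 0 lower of 17, percentile 100, and 0.90 with at least 1000 genes, 16 higher and 1 lower, percentile 100), with Top2a in 16 of 72 against 1 of 26. In the osteoblast list (median -0.51 over all cells, 4 higher and 11 lower of 15, percentile 0, and -1.19 with at least 1000 genes, 4 higher and 11 lower, percentile 0) the collagens Col1a1 and Col1a2 were higher. The fibroblast and periosteal list (median 0.47 over all cells, 9 higher and 2 lower of 12, percentile 93.5, and 0.67 with at least 1000 genes, 9 higher and 2 lower, percentile 99.9) lay inside the central 95% of random lists over all cells, as did, in cells matched on detected genes, the tendon (percentile 90.8) and proliferation lists (97).

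Pericyte and smooth muscle genes were higher in THY+ (median 1.30 over all cells, 10 higher and 1 lower of 11, percentile 100, and 2.18 with at least 1000 genes, 10 higher and 1 lower, percentile 100). Rgs5, a pericyte regulator of G protein signalling, was detected in 19 of 72 cells (26.4%, 16.7 to 38.1) of THY+ and 1 of 26 cells (3.85%, 0.097 to 19.6) of CSP. Pdgfrb was detected in 32 of 72 against 0 of 26 and Higd1b in 11 of 72 against 0 of 26 cells. Among the 43 THY+ cells with at least 1000 genes, 30 held 0 to 4 of the 11 transcripts and 13 held 6 to 11. The index plate differed with the population here, so plate and population cannot be told apart. The ribosomal protein list turned (median 1.0 over all cells, 75 higher and 7 lower of 84, percentile 97.9, and -0.75 with at least 1000 genes, 5 higher and 77 lower, percentile 50.1).

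**Figure D3:**
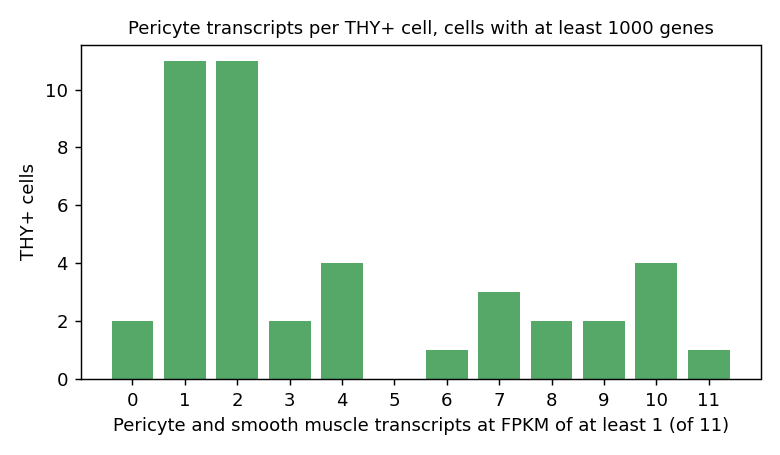
Number of THY+ cells with at least 1000 genes (vertical axis) by how many of 11 pericyte and smooth muscle transcripts each held at FPKM of at least 1 (horizontal axis). Of the 43 cells 30 hold 0 to 4, none holds 5 and 13 hold 6 to 11.

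In 6C3+ cells Col1a1, Col3a1 and Prg4, which encodes the joint lubricant lubricin, were higher than in cells labelled CSP. Col1a1 was detected in 77 of 92 cells (83.7%, 74.5 to 90.6) of 6C3+ and 2 of 26 cells (7.69%, 0.946 to 25.1) of CSP, a difference of 5.86. Prg4 was detected in 46 of 92 cells (50%, 39.4 to 60.6) against 1 of 26 cells (3.85%, 0.097 to 19.6) and Col3a1 differed by 3.65. Matn1 was not detected in any of the 92 6C3+ cells and was detected in 16 of 26 CSP cells; among the 34 6C3+ cells with at least 1000 genes the 95% interval of the share reaches 10.3%. Pth1r (-5.47), Col9a2 (-5.25), Col2a1 (-5.18) and Col11a2 (-4.73) were lower.

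With at least 1000 genes Col1a1 differed by 8.36, Lgals1 by 6.56, Prg4 by 5.72 (25 of 34 against 1 of 11) and Gas1 by 4.53. Matn1 (-9.84), Ppa1 (-8.97), Mia (-7.83), Matn3 (-7.50) and Epyc (-6.74) were lower. All 15 chondrocyte genes were lower over all cells (median -3.85) and with at least 1000 genes (-5.11), although Col2a1 was still detected in 62 of 92 6C3+ cells. Fibroblast and periosteal genes were higher (median 0.57 over all cells, 8 higher and 2 lower of 12, percentile 100, and 1.44 with at least 1000 genes, 8 higher and 2 lower, percentile 100), with Pdgfra in 25 of 34 against 0 of 11 cells and Lum lower (-4.34). Tendon genes were higher (median 0.49 over all cells, 5 higher and 2 lower of 7, percentile 100, and 0.85 with at least 1000 genes, 5 higher and 2 lower, percentile 99.7), with Thbs4 in 16 of 34 against 0 of 11. Proliferation genes were higher (median 0.23 over all cells, 14 higher and 3 lower of 17, percentile 100, and 0.66 with at least 1000 genes, 15 higher and 2 lower, percentile 100). The osteoblast list was lower (median -0.51 over all cells, 3 higher and 11 lower of 15, percentile 0.5, and -1.19 with at least 1000 genes, 3 higher and 11 lower, percentile 0.1). In cells matched on detected genes the tendon (percentile 91.4) and proliferation lists (95.2) lay inside the central 95% of random lists. Plate and population cannot be told apart in this comparison either, and 58 of the 92 6C3+ cells lay under 1000 genes. Prg4 lies on chromosome 1 (150449412 to 150466165, minus strand) of mm10.

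Between the 2 populations named for a positive stromal antigen, 6C3+ cells had more Prg4 and, with at least 1000 genes, a higher mean of several chondrocyte transcripts that a part of the cells carried, and THY+ cells had more pericyte and smooth muscle transcripts. Prg4 was detected in 46 of 92 cells (50%, 39.4 to 60.6) of 6C3+ and 20 of 72 cells (27.8%, 17.9 to 39.6) of THY+, a difference of 1.76, and in 25 of 34 against 14 of 43 cells with at least 1000 genes (4.19). In those cells Scrg1 (3.07), Col2a1 (2.83), Chad (2.76), Col9a2 (2.63) and the WNT inhibitor Wif1 (2.66) were higher in 6C3+. Without the cluster of 9 cells described below the differences were 1.52, 0.90, 1.46, 1.04 and 1.19 in that order, and without it and a cluster of 6 cells -0.10, -1.11, -0.38, -0.56 and -0.42; Prg4 differed by 2.62 and 1.31. Some of these genes are among those that lead the clusters, so their removal lowers the values by choice of cells. Lower were Col4a1 (-3.98; 17 of 34 against 36 of 43), Marcks (-3.51), Tmsb4x (-3.22), Postn (-3.10) and Vim (-2.78). Over all cells Postn (-3.40), Vim (-3.46) and Tmsb4x (-3.29) were lower as well, where the median over all genes was -0.98. With at least 1000 genes that median was -0.35, and the median endogenous total was 366748 FPKM in 6C3+ and 752613 in THY+ cells.

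All 11 pericyte and smooth muscle genes were lower in 6C3+, with a median of -1.26 over all cells and -2.06 with at least 1000 genes, both at percentile 0. Acta2 was detected in 2 of 34 6C3+ and 15 of 43 THY+ cells and Higd1b in 1 of 34 and 11 of 43. Adipocyte genes were lower (median -0.46 over all cells, 0 higher and 4 lower of 6, percentile 0.1, and -0.67 with at least 1000 genes, 0 higher and 4 lower, percentile 0.1), with Lpl in 4 of 34 against 12 of 43 and Cebpa in 1 of 34 against 10 of 43. The chondrocyte list turned with the cells used: 5 of 15 genes were higher over all cells (median -0.094) and 12 with at least 1000 genes (median 0.92), at percentile 100 in both; without the cluster of 9 cells 8 of 15 were higher (median 0.16), and without both clusters 1 (median -0.90). Rescaling all cells to an equal total also gave a positive median, 0.28. The fibroblast list turned likewise, from -0.29 to 0.19; Ly6a was detected in 11 of 34 against 3 of 43 and Dcn in 23 of 34 against 19 of 43. The plates differed between these populations too, and their gates differ in Thy, 6C3 and Tie2.

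**Figure D4:**
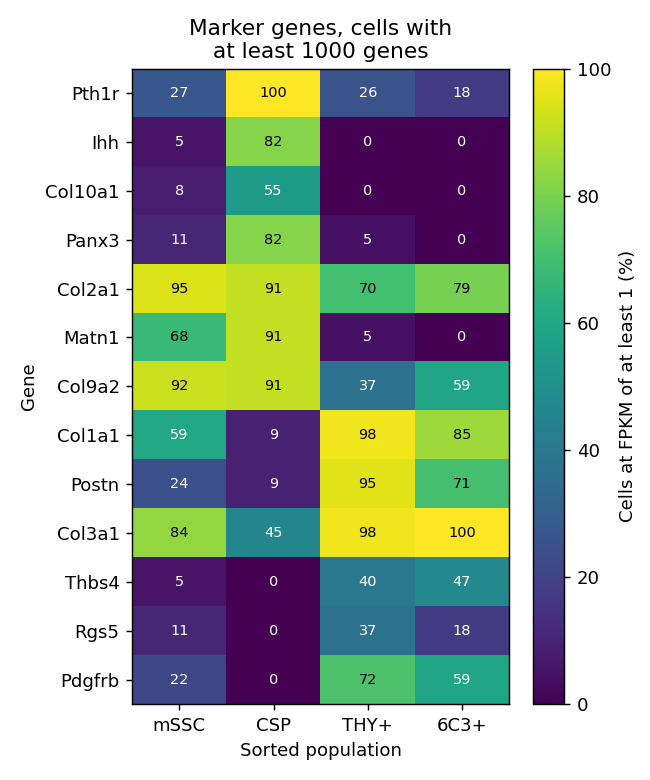
Percent of cells at FPKM of at least 1 (colour and printed value) for 13 marker genes (rows) in the 4 populations (columns), cells with at least 1000 genes. Ihh reaches 81.8% in CSP and is not detected in THY+ or 6C3+ cells, while Col1a1 reaches 97.7% in THY+ and 9.09% in CSP cells.

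Averaged over the members of the list and all cells, endothelial genes were detected in 2.34% of mSSC, 0% of CSP, 2.87% of THY+ and 1.30% of 6C3+ cells, most often as Erg and, in THY+, Esam. Outside mSSC no myeloid or pre-B gene was detected in any cell, and in mSSC Lyz2, Laptm5, Coro1a and Cd79a were each detected in 1 of 37 cells. The osteoclast gene Acp5 was detected in 1 of 37 mSSC and 1 of 92 6C3+ cells. The erythroid gene Hbb-bs was detected in 2 of 37 mSSC and 1 of 72 THY+ cells. S100b, a Schwann cell marker that chondrocytes also express, was detected in 30 of 37 mSSC cells, whereas Sox10 was not detected in any cell. Of the skeletal muscle genes, Acta1 was detected in 19 of 37 mSSC and 17 of 72 THY+ cells, and Myod1 in none. With at least 1000 genes the average over the skeletal muscle list was 10.8% of mSSC, 15.2% of CSP, 11.6% of THY+ and 3.92% of 6C3+ cells. For the Schwann list it was 20.9%, 18.2%, 7.56% and 7.35% in that order.

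Clustering each population alone mainly separated cells by their number of detected genes in CSP, THY+ and 6C3+. It gave 2 clusters in each, with median gene numbers of 3033 and 580 in THY+ and 2664 and 258 in 6C3+, and the larger median in CSP was 3033. The 37 mSSC cells were placed in 6 clusters of 3 to 11 cells with a silhouette of 0.121. Values of mSSC shuffled over cells also gave 6 clusters, with a silhouette of 0.079. With 20 principal components or with k-means the mSSC cells fell into 2 clusters. No cluster had, among its 50 leading genes, 3 markers of a single cell type list and none of another, so none was given a cell type name. In 6C3+ cells with at least 1000 genes, 1 cluster of 9 cells had the chondrocyte genes Lect1, Col2a1, Col9a1 and Col9a2 among its 10 leading genes, with the dissociation stress gene Nr4a1; the tendon gene Fmod was among the 50. Another cluster of 6 cells had Chad, Col2a1 and the dissociation stress gene Atf3 among its 10. In the same set a cluster of 8 cells was led by Tmsb4x, Ly6a and Uhrf1.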

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

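The tests on spike-ins and nuclear RNA were chosen only after the result was seen; the carry-over test was chosen before. ERCC spike-ins, which no comparison uses, took a median of 52.8% of FPKM in THY+ cells and 75.8% in 6C3+ cells, a signal outside the main measurement.

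The pattern weighed is the set of cells with under 1000 genes in CSP, THY+ and 6C3+, unevenly spread over index rows in THY+, with 2 of 22 cells (1.12 to 29.2%) in the first 2 rows and 27 of 50 cells (39.3 to 68.2%) in the others, but not in that direction in 6C3+, with 16 of 22 cells (49.8 to 89.3%) and 42 of 70 cells (47.6 to 71.5%). Fewer reads from the same amount of cell RNA is argued against in THY+ and 6C3+, because the spike-in share was larger there: in 6C3+ its quartiles were 77.6% and 97.6% under 1000 genes against 12.3% and 23.1% over, and in THY+ 94.9% and 98.3% against 11.8% and 36.9%; with the first 2 rows left out the lower quartile was 96% against an upper quartile of 62.4% in THY+ and 93.5% against 25.8% in 6C3+. Carry-over from neighbouring wells stays open for CSP: 60% of its cells under 1000 genes (9 of 15, 32.3 to 83.7) had a larger CSP share than the plate's 15.3%, and the test needed over 75% to exclude it; their median CSP share, 76.1%, and pooled share, 80.9%, were near those of CSP cells over 1000 genes (82.6% and 68.8%), which goes against carry-over, but the quartiles, 2.53% and 96.2%, span the plate's share. Loss of cytoplasmic RNA stays open too: the share of Malat1, Neat1 and Meg3 under 1000 genes was 6.72 times that over 1000 in THY+ and 9.1 times in 6C3+, but 0.893 times in CSP, so such loss may contribute in THY+ and 6C3+. No biological explanation was tested.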

How the results depend on the processing

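Tests on cells with at least 1000 or 2000 genes were chosen only after the data were seen; the other settings were chosen before the data were examined. No paired analysis was possible because the sample numbers only count single cells and no result comes from a test. Values that moved past their interval or their spread over cells, or reversed, were counted for each setting. They were 1 moved and 0 reversed with a pseudocount of 0.1, 0 moved and 1 reversed with 10, 2 moved and 1 reversed with each cell rescaled to 1000000, 9 moved and 0 reversed with genes at mean FPKM of at least 1, 0 without the 10% of cells with the fewest genes, 17 moved and 7 reversed in cells matched on detected genes, 33 moved and 4 reversed and 31 moved and 4 reversed in cells with at least 1000 and 2000 genes, 40 moved and 8 reversed with at least 1000 genes and rescaling, and 55 moved and 2 reversed with the log2 of the mean. Leaving out cells with endothelial transcripts removed no cell, so that setting is void. Depth in reads is unknown, and each population counted as 1 sample, so no setting measures variation between animals. Rescaling moved the median over all genes in CSP minus mSSC from -1.43 to -1.11. The cause of each change below was not tested.

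For the sort antigen transcripts, counting any FPKM above 0 put Itgav at 83.8% of mSSC and 50% of THY+ cells. At FPKM of at least 10 Itgav was at 45.9% of mSSC, 25% of THY+ and 9.78% of 6C3+, Eng at 5.56% of THY+ and Tek at 0.0% of 6C3+ cells. With at least 1000 genes Cd200 was at 81.8% of CSP, 30.2% of THY+ and 32.4% of 6C3+, Enpep at 26.5% of 6C3+, and Itgav at 63.6% of CSP, 60.5% of THY+ and 64.7% of 6C3+ cells. The median gene number there was 3033 in CSP and 2639 in 6C3+. The largest mSSC cluster took 48.6% of cells with 1000 variable genes, 59.5% with 20 principal components and 62.2% with k-means. The number of mSSC clusters was 5, 2 and 2 in that order.

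With at least 1000 genes, at least 2000 genes, and at least 1000 genes with rescaling, in that order, the list medians were as follows. The hypertrophic list was at 4.53, 4.62 and 5.05 in CSP minus mSSC, -4.74, -4.83 and -5.27 in THY+ minus CSP, and -4.75, -4.83 and -5.29 in 6C3+ minus CSP. In THY+ minus CSP the chondrocyte list was at -6.79, -7.11 and -7.01 and the ribosomal list reversed to -0.75, -0.27 and -0.98. In 6C3+ minus THY+ the chondrocyte list reversed to 0.92, 0.73 and 1.94, the fibroblast list to 0.19, 0.19 and 0.47, and the BMP list to 0.14, 0.23 and 0.50. In CSP minus mSSC the osteoblast list was at 1.46 with at least 2000 genes and the chondrocyte list at 0.70 with rescaling. With rescaling, 6C3+ minus THY+ reversed for the ribosomal list (0.63), Col1a2 (0.16), Col3a1 (0.28) and Hsp90ab1 (0.18).

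In cells matched on detected genes, which left 4 CSP cells, the osteoblast list was at 1.54 in CSP minus mSSC. Reversed there were Mgp in CSP minus mSSC (0.067), the ribosomal list in THY+ minus CSP (-0.046), TGF beta (-0.76) and Dnm1 (-0.70) in 6C3+ minus CSP, and the chondrocyte (1.36), fibroblast (0.032) and BMP (0.15) lists in 6C3+ minus THY+. With all cells rescaled the chondrocyte list reversed to 0.28 in 6C3+ minus THY+, and with a pseudocount of 10 the BMP list reversed to 0.025 in THY+ minus CSP.

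With the log2 of the mean, CSP minus mSSC gave 4.35 for the hypertrophic, 1.76 for the osteoblast, -1.43 for the marrow stroma, -2.29 for the pericyte, -2.41 for the tendon and -4.04 for the proliferation list. THY+ minus CSP gave -6.53 for the hypertrophic, -3.09 for the osteoblast, 3.15 for the marrow stroma, 5.58 for the pericyte, 2.41 for the fibroblast and 3.47 for the proliferation list, and the BMP list reversed to 0.80. 6C3+ minus CSP gave -7.68 for the hypertrophic, -2.30 for the osteoblast, 0.89 for the marrow stroma and 2.16 for the proliferation list, and Meg3 reversed to -0.075. 6C3+ minus THY+ gave -2.18 for the marrow stroma and -4.60 for the pericyte list.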

Other observations

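Tests of the Cd200 and Eng pattern and of 8 or more pericyte transcripts were chosen only after the result was seen; those of 5 or more transcripts and of Rgs5 as background were chosen before. The WNT list in THY+ minus CSP (median 0.38 over all cells, 13 higher and 1 lower of 14, percentile 94.6, and 0.42 with at least 1000 genes, 11 higher and 3 lower, percentile 94.7) lay inside the central 95% of random lists. Among cells with at least 1000 genes the secreted modulator gene Dkk3 was detected in 32 of 43 THY+, 23 of 34 6C3+, 1 of 11 CSP and 7 of 37 mSSC cells, and Nkd2 in 6 of 43 THY+ cells and no cell of the other populations, and the BMP target gene Id3 was detected in 35 of 37 mSSC and 10 of 11 CSP cells, against 28 of 43 THY+ and 25 of 34 6C3+. The BMP list in CSP minus mSSC (median -1.05 over all cells, 2 higher and 11 lower of 13, percentile 24.4, and -0.22 with at least 1000 genes, 5 higher and 8 lower, percentile 14.9) lay inside the central 95% of random lists, and in THY+ minus CSP (median -0.12 over all cells, 6 higher and 7 lower of 13, percentile 0.9, and -0.93 with at least 1000 genes, 5 higher and 8 lower, percentile 0.7) below it; there it turned to 0.80 with the log2 of the mean (percentile 35.4) and 0.025 with a pseudocount of 10 (7.7), and lay at percentile 3 with at least 1000 genes and rescaling, so the call depends on the setting. In 6C3+ minus THY+ the BMP list lay above the central 95% at percentiles 99.75 over all cells and 98.7 with at least 1000 genes. Its median turned from -0.17 to 0.14 between them. There it lay inside at percentile 94.9 in cells matched on detected genes and 96.1 with at least 1000 genes and rescaling. With at least 1000 genes the hedgehog gene Gli3 was detected in 24 of 43 THY+ and 6 of 37 mSSC cells. The TGF beta list in THY+ minus CSP (median 0.54 over all cells, 6 higher and 3 lower of 9, percentile 88.5, and 0.41 with at least 1000 genes, 6 higher and 3 lower, percentile 89.3) lay inside the central 95% and in 6C3+ minus CSP (median 0.17 over all cells, 6 higher and 3 lower of 9, percentile 98.7, and 0.42 with at least 1000 genes, 6 higher and 3 lower, percentile 98.0) above it, but there it turned to -0.76 in cells matched on detected genes (percentile 32.3) and lay inside at percentiles 92.5 with a pseudocount of 10, 90.1 with the log2 of the mean and 91.3 with at least 2000 genes. With at least 1000 genes Tgfbr3 was detected in 17 of 34 6C3+ and 1 of 11 CSP cells. The limb gene Tbx4 was detected in 15 of 34 6C3+ and 8 of 43 THY+ cells and Prrx1 in 16 of 34 and 33 of 43.

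Cd200 was detected in 81.8% of CSP and 21.6% of mSSC cells with at least 1000 genes, but the CSP gate does not name CD200. Eng was detected in 21.6% of mSSC and 0% of CSP cells, opposite to the CD105 gates but with overlapping intervals. In the other CD105+ gates Eng was detected in 8.82% of 6C3+ and 23.3% of THY+ cells. The Cd200 intervals of CSP and mSSC lie apart, at 48.2 to 97.7 and 9.83 to 38.2, but the gene numbers of these cells differ (medians 3033 and 2534). In cells matched on detected genes Cd200 was found in 4 of 4 CSP (39.8 to 100) and 6 of 27 mSSC cells (8.62 to 42.3), a gap no smaller than before; a difference in detected genes stays open only because 4 CSP cells are too few for these intervals to part, and a bound on matched cells was set after both values were seen. An exchange of the 2 labels may underlie the pattern and stays open. The CSP gate sets no CD200 level, and the Eng intervals overlap (0 to 28.5 in CSP and 9.83 to 38.2 in mSSC). A biological difference between surface antigen and transcript stays open as well and was not tested.

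In THY+ cells with at least 1000 genes 13 held 5 or more of the 11 pericyte and smooth muscle transcripts, against 14.2 given by independent detection, which decides nothing because detection shares this high already give about that many. Background spread over all cells is argued against: the 13 cells with 5 or more of the other 10 transcripts, 30.2% of cells, held 99.6% of the summed Rgs5 FPKM. With 8 or more transcripts the count was 9 cells, against 0.38 under independence, which leaves out that cells differ in gene number, and a median of 1 and a highest of 7 in 10000 random sets of 11 genes with detection counts within 1 cell of these, in the same cells. A separate set of pericyte-like cells inside the THY+ gate is a candidate explanation, found and tested on the same data, but clustering these 43 cells did not show it: it gave clusters of 34 and 9 cells that differed in gene number (medians 3151.5 and 1879), with no pericyte transcript among the 50 leading genes of either. Doublets were not tested; the labels state that only sites holding a single live cell were kept.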
